A study of Mus musculus with 6 samples.

How the data were processed

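RNA of sorted lineage-negative, Sca1-positive, cKit-positive bone marrow cells (LSK cells) was measured in 6 samples, 3 labelled Tifab wild type and 3 labelled Tifab knockout, on Affymetrix MoGene ST arrays with 1 array per sample. Per the labels' protocols, the mice carried transplanted marrow of either genotype, the lethally irradiated Boy/J recipients received 7 and 4.75 Gy 3 hours apart, total RNA was purified on Zymo columns, and cDNA was amplified with the NuGEN Ovation Pico kit and labelled with biotin. The labels give 3 months without settling whether this is an age or a time after transplantation, and they do not state whether a donor marker was part of the sort. Each group has 3 mice per the labels, and samples are named here by genotype label and replicate number.

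The authors deposited 1 table of log2 probe set values, 41345 probe sets by 6 arrays, running from about 0.83 to 13.5. Per the submitters' processing notes, the values came from Affymetrix Expression Console. The background correction, the summary method, the normalization, the version and any filter are not given in the sources used here. The array medians over all probe sets lay between 4.05 and 4.10 on the log2 scale, so the deposited values had been brought to a common scale before this work, and no further normalization was applied for the main results. A normalization that equalises whole arrays would hide a change in total RNA per cell, and values near the floor of the array compress fold changes.

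Probe sets were named through the platform annotation table supplied for the array. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not listed and stay unnamed here. Entrez identifiers of 23328 probe sets matched the RefSeq gene table of GRCm38.p6, which changed 0 symbols and was otherwise used only for the order of neighbouring genes. Probe sets with several symbols were left out. For the 1082 genes with several probe sets, the one with the highest mean over all 6 arrays stood for the gene, which left 22180 genes. No pair of arrays held identical values, while 802 probe sets repeated the values of another probe set.

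Knockout-labelled and wild-type-labelled arrays were compared with limma (lmFit and eBayes with an intensity trend) in a model with genotype as the only term, two-sided, with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. Fold changes are knockout minus wild type by label, in log2 units. A looser count used an unadjusted p under 0.05 and at least 1.5-fold. Gene lists were tested with camera in limma at its preset inter-gene correlation of 0.01, with adjustment over 20 lists, beside camera with an estimated correlation and fry. The limma p values of members were also adjusted over each list alone. That adjustment does not correct for the number of lists, so a member passing it is not a call over all genes. The lists covered Toll-like receptor and TRAF6 components, NF-kB targets, interferon-stimulated genes, long-term stem cell genes, lymphoid-primed, granulocyte and macrophage and megakaryocyte and erythroid programmes, cell cycle, p53 targets, immediate early genes, ribosomal proteins, oxidative phosphorylation, MHC class II and dendritic cells, neutrophils, macrophages, B and plasma cells, T and NK cells, mast cells with basophils and eosinophils, stroma and endothelium, and genes next to Tifab. A further list of 4 measured sex-linked genes served as a check and was not tested: over the 6 arrays Xist lay between 9.31 and 10.2 and the Y-linked Eif2s3y between 6.27 and 6.79, Uty between 4.27 and 5.15 and Kdm5d between 4.23 and 5.57, and no sex is read from them here. List members without a probe set of their own were not analysed here.

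The groups, the tests, the lists, the rule for named genes and all alternatives except cyclic loess were set before the data were examined. By that rule the text names Tifab, up to 12 genes with the largest rise and 12 with the largest fall among genes past the adjusted threshold whose groups do not overlap, and up to 4 members per list with the smallest p, or 6 for a list that passed. Where fewer than 12 genes passed, the places went to the largest differences among non-overlapping genes past the looser threshold whose higher group mean exceeded the median of all genes, given as values. Predicted or unstudied genes, small RNA genes, receptor and immunoglobulin segments and sex-linked genes were skipped: 46 of 165 eligible genes in the higher direction and 20 of 93 in the lower. Genes named outside the rule are marked as chosen after their values were seen.

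Alternatives were eBayes without the trend, robust eBayes, array weights, quantile normalization, median centring, leaving out genes under the 40th percentile of mean signal, the mean of a gene's probe sets, the replicate number as a block, each array left out in turn, every probe set, an adjusted p under 0.1, no moderation of the spread, a 2-fold threshold, camera on ranks and lists without shared members. Cyclic loess between arrays was added after the data had been seen, as was a comparison of each list's median with 10000 random lists of equally bright genes, which leaves out correlation between genes. The method was tested on simulated data for 22180 genes in 3 arrays against 3, over 20 simulations: at adjusted p under 0.05 it recovered 50.1% of genes changed 2-fold, 92.3% of those changed 4-fold and 98.9% of those changed 8-fold, with a mean of 5.8 unchanged genes called per simulation. Genes of all these sizes were changed together in each simulation, and the recovered share depends on how many genes change. With fewer changed genes it could be lower. A list shifted by 0.2 log2 units was called in 100% of simulations. The simulated genes were drawn independently of each other, so this result does not cover lists whose members are correlated. The number of arrays, 3 per group with 4 residual degrees of freedom, limits the precision: the median standard error of a log2 fold change was 0.17. A two-sided exact test of 3 arrays against 3 cannot give a p below 0.1. Computations used R 4.3.3 and limma 3.58.1, and figures Python 3.11.15 and matplotlib 3.10.9.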

Results

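LSK cells, the bone marrow fraction that holds hematopoietic stem cells and multipotent progenitors, were profiled in mice transplanted with marrow labelled Tifab wild type or Tifab knockout. Tifab encodes a protein related to TIFA, an adaptor of the TRAF6 pathway. The series asks how the expression profile of these cells differs between the genotypes after engraftment, and its title names Toll-like receptor and TRAF6 signalling. Each group had 3 arrays. Over 22180 genes the arrays correlated at r = 0.985 to 0.986 within the knockout label, 0.976 to 0.979 within the wild-type label and 0.975 to 0.983 between labels, all across genes, which are not independent replicates. Wild-type replicate 1 had the lowest mean correlation with the other arrays, 0.976.

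The knocked-out gene itself did not separate the groups. The Tifab probe set read 4.99, 5.37 and 5.53 in the wild-type-labelled arrays and 5.21, 5.12 and 5.26 in the knockout-labelled arrays, a log2 fold change of -0.10 ± 0.18 (SE, adjusted p = 0.885 in limma). Where its probes lie relative to the deleted part of the gene is not given in the sources used here. This probe set therefore gives no check on the labels, and every direction below rests on them. Among the genes named here the lowest p was at Macroh2a1, which encodes the histone variant macroH2A1 and is the immediate neighbour of Tifab among measured genes in the gene order of GRCm38.p6. Macroh2a1 measured 9.96 ± 0.07 (SD, n = 3) in the wild-type-labelled arrays and 9.06 ± 0.16 (SD, n = 3) in the knockout-labelled arrays, a log2 fold change of -0.90 ± 0.11 (SE) or 0.538 of the wild-type-labelled level. It was lower in 3 of 3 knockout-labelled arrays. Its adjusted p of 0.186, the lowest over all genes and shared with a small RNA gene, missed the threshold. Adjusted over the list alone, among 24 measured genes fixed in advance and listed as next to Tifab, it passed at 0.000403. This list was matched by gene name, and the mouse positions of its other members were not checked. The neighbour list as a whole did not pass (camera adjusted p = 0.665), with Trpc7 at 0.48 ± 0.18 (SE), Tgfbi at -0.35 ± 0.15 (SE) and Catsper3 at -0.34. Trpc7 and Catsper3 lay near the bottom of the signal range and had 0.30 without wild-type replicate 1 and -0.23 without wild-type replicate 3.

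**Figure D1:**
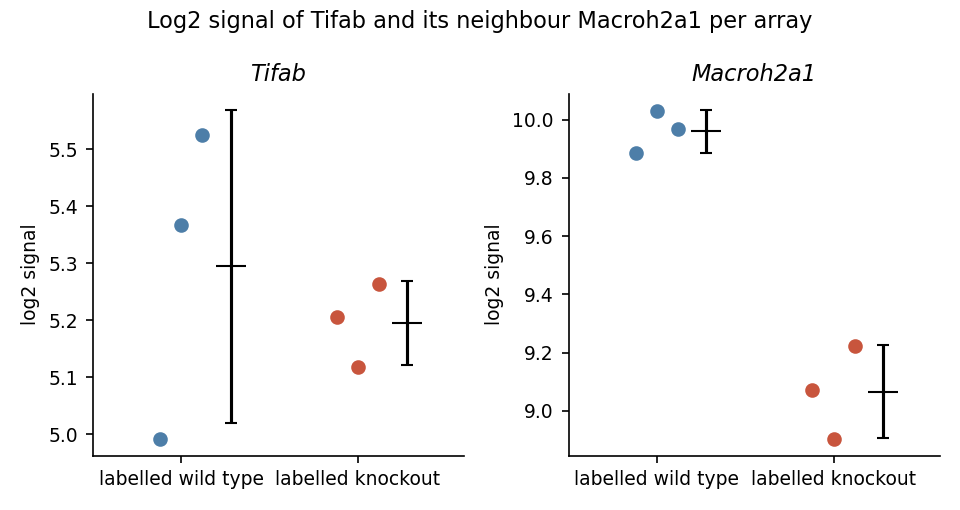
Log2 signal of Tifab (left) and Macroh2a1 (right) in each array, by genotype label; points are arrays, and bars give the mean and SD of 3 arrays. The Tifab values overlap, while the 3 knockout-labelled arrays lie between 8.90 and 9.22 for Macroh2a1, all below the wild-type-labelled arrays at 9.88 to 10.03.

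No gene passed the adjusted threshold of 0.05 in limma. At an unadjusted p under 0.05 there were 2274 genes, where 1109 would be expected by chance, 1052 of them higher and 1222 lower in the knockout-labelled arrays. Without moderation of the spread, 1953 genes had an unadjusted p under 0.05 and 0 passed the adjusted threshold. The groups did not overlap for 16.1% of genes, where chance gives 10%. An unadjusted p under 0.05 with at least 1.5-fold held for 605 genes, 287 higher and 318 lower. The higher set lay at brighter signals: 73.5% of it and 38.4% of the lower set had a higher group mean above the median of all genes. Leaving out wild-type replicate 3 raised this count to 1095, and leaving out genes under the 40th percentile of signal lowered it to 356, of which 222 were higher. Median centring gave 189 higher and 474 lower. Without wild-type replicate 3 the immunoglobulin gene Iglv1 passed the adjusted threshold (log2 fold change 2.86, adjusted p = 0.0133), and without knockout replicate 2 the eosinophil gene Prg2 did (-2.83, adjusted p = 0.0177).

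Among the genes with the largest differences that did not overlap, given as values since none passed, the interferon-inducible chemokine gene Cxcl9 measured 5.54 ± 0.22 (SD, n = 3) in the wild-type-labelled and 7.21 ± 0.83 (SD, n = 3) in the knockout-labelled arrays, a log2 fold change of 1.67 ± 0.35 (SE, adjusted p = 0.297). Fbp1, a fructose bisphosphatase of gluconeogenesis, differed by 1.35 ± 0.25 (SE). Ly6c2, a surface antigen of monocytes and their progenitors, was at 10.25 in the wild-type-labelled and 11.38 in the knockout-labelled arrays. Atp5g1, a subunit of mitochondrial ATP synthase, had a log2 fold change of 1.26, and the lymphoid surface genes Clec2d and Cd7 had 0.98 and 0.96. The others with higher values were Slc12a4, Meak7, Nuak2 and the zinc-finger genes Zfp119a, Zfp689 and Zfp729a, at 0.94 to 1.26. In the other direction, Il1r2, a decoy receptor for interleukin-1, measured 5.07 ± 0.88 (SD, n = 3) and 3.74 ± 0.16 (SD, n = 3), a log2 fold change of -1.33 ± 0.37 (SE, adjusted p = 0.344). Plaur, the urokinase receptor gene, was at 7.90 and 6.86. Acads, a mitochondrial acyl-CoA dehydrogenase, was at 7.40 and 6.41, with 1 wild-type-labelled array at 8.59 and the other 2 at 6.66 and 6.95. Tlcd1, Tmem108, Efcab2, Zfp874a, Chad, Zfp932, Syt11, Obox5 and Abcb4 had log2 fold changes of -0.95 to -1.38. Further probe sets of Tlcd1, Tmem108 and Slc12a4 gave 0.29, 0.04 and 0.21, so these genes' values belong to single probe sets. Several values rested on 1 array: without wild-type replicate 1, Acads had -0.40, Zfp932 -0.42, Syt11 -0.65 and Il1r2 -0.82, and without knockout replicate 3, Meak7 had 0.52 and Tlcd1 -0.87.

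Genes of the pathway named in the title were set out in 2 lists. The NF-kB target and feedback genes fell as a list: 33 of 47 measured members were lower and 14 higher, with a median log2 fold change of -0.16 (camera adjusted p = 0.0101; adjusted p = 0.319 with an estimated correlation). At an unadjusted p under 0.05, 8 members were lower, 2 were higher and 37 were neither; 0 passed over all genes and 2 passed adjusted over the list alone. These 2 were Nfkbie, an inhibitor of NF-kB that is itself an NF-kB target, at 7.24 ± 0.10 against 6.54 ± 0.08 (SD, n = 3 each, log2 fold change -0.70 ± 0.14, SE, list-alone adjusted p = 0.0162), and the cytokine gene Il1b, at 5.12 ± 0.18 against 4.27 ± 0.18 (SD, n = 3 each, log2 fold change -0.85 ± 0.17, SE, list-alone adjusted p = 0.0162). Nfkbia, the gene of the inhibitor IkB-alpha, had a log2 fold change of -0.33 ± 0.09 (SE), the adhesion molecule gene Vcam1 -0.74 and the chemokine gene Cxcl2 -0.51, while the chemokine gene Ccl3 was on the higher side at 0.39, or 0.24 without wild-type replicate 1. The mature neutrophil list was lower in the same arrays, with a median of -0.13. Without wild-type replicate 1 the NF-kB list missed the threshold (adjusted p = 0.143).

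The Toll-like receptor and TRAF6 signalling components did not pass. Of 54 measured members, 29 were lower and 25 higher, with a median log2 fold change of -0.08 (camera adjusted p = 0.491). The 3 members with an unadjusted p under 0.05 were lower: Sqstm1, which encodes the p62 scaffold protein that binds TRAF6, at -0.56 ± 0.14 (SE), Il18r1, a receptor for interleukin-18, at -0.45 ± 0.16 (SE), and Irak3, a negative regulator of Toll-like receptor signalling, at -0.36 ± 0.15 (SE). Tlr6 had -0.41, or -0.27 without wild-type replicate 1. None of the 54 passed adjusted over the list alone. The immediate early and stress genes, many of which answer the same signals and cell handling, did not pass with the values as deposited (median -0.07 over 41 genes, camera adjusted p = 0.137); Jund had -0.34, Nr4a1 -0.27, Fosl2 -0.75 and Btg1 -0.39. This list passed as lower after quantile normalization (adjusted p = 0.00185, the lowest over all alternatives), without dim genes (0.0204), after cyclic loess (0.00215), without wild-type replicate 3 (0.00394) and without knockout replicate 1 (0.0330). These calls used camera at the preset correlation. The estimated correlation was 0.139, and with it the adjusted p was 0.772 as deposited, the highest over all alternatives, and 0.663 after cyclic loess.

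The interferon-stimulated genes rose as a list in the knockout-labelled arrays. Of 47 measured members, 32 were higher and 15 lower, with a median log2 fold change of 0.14 (camera adjusted p = 0.00152; adjusted p = 0.319 with an estimated correlation). Among the members, 12 were higher at an unadjusted p under 0.05, 2 were lower and 33 were neither; 0 passed adjusted over the list alone. The apoptosis-linked gene Xaf1 measured 6.47 ± 0.24 against 7.17 ± 0.09 (SD, n = 3 each, log2 fold change 0.70 ± 0.16, SE). The immunity-related GTPase gene Irgm2 had 0.87 ± 0.24 (SE), the oligoadenylate synthetase gene Oas2 0.82 ± 0.25 (SE), Ifit1 0.51 ± 0.17 (SE), and Dhx58, which encodes the RNA sensor LGP2, 0.50 ± 0.17 (SE). Ifit3b went the other way at -0.44 ± 0.15 (SE), near the bottom of the signal range. Leaving out any single array kept the list past the threshold, with adjusted p of 0.0437 or less.

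**Figure D2:**
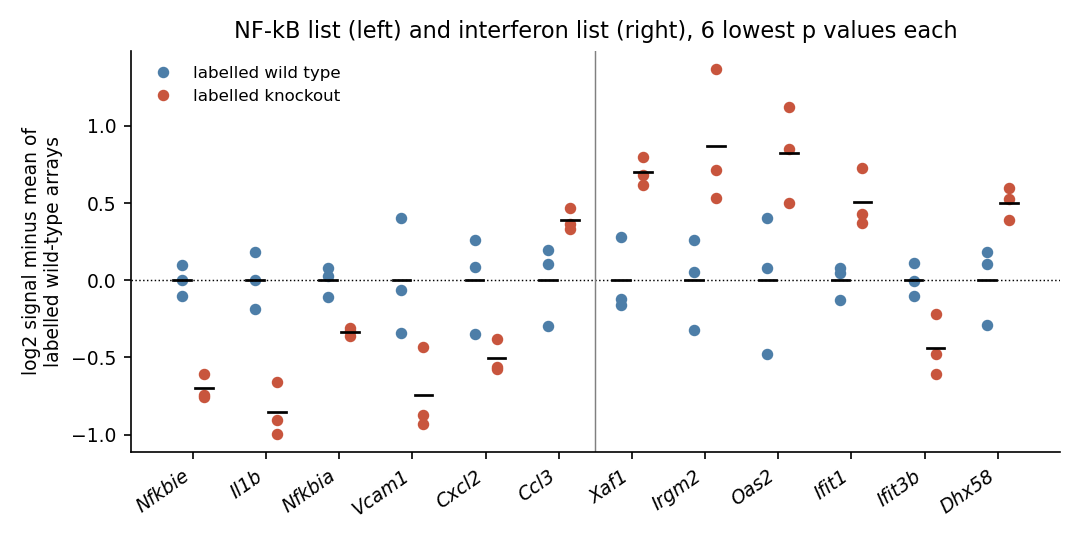
Log2 signal of the 6 genes with the lowest p in the NF-kB list (left) and in the interferon-stimulated list (right), minus the mean of the wild-type-labelled arrays; points are arrays and short lines the means of 3 arrays. Nfkbie, Il1b, Nfkbia, Vcam1 and Cxcl2 lie lower in the knockout-labelled arrays (-0.33 to -0.85) and Xaf1, Irgm2, Oas2, Ifit1 and Dhx58 higher (0.50 to 0.87), while Ccl3 and Ifit3b go against their lists.

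Among the stem and progenitor programmes, only the granulocyte and macrophage progenitor genes passed the camera test, as higher. Of 39 measured members 28 were higher and 11 lower, with a median log2 fold change of 0.13 (camera adjusted p = 0.0328; adjusted p = 0.612 with an estimated correlation). At an unadjusted p under 0.05, 3 were higher and 1 was lower: Ly6c2, the granule protease gene Ctsg at 9.97 ± 0.03 against 10.38 ± 0.18 (SD, n = 3 each), F13a1, a coagulation factor gene of monocytic cells, at 0.62 ± 0.21 (SE), and Gstm1 at -0.37. The elastase gene Elane had 0.51 ± 0.24 (SE), with 1 knockout-labelled array at 10.8 and the others at 9.75 and 9.87 (0.16 without knockout replicate 3), and Csf3r, the G-CSF receptor gene, 0.26 ± 0.13 (SE). The list missed the threshold without wild-type replicate 1 (adjusted p = 0.458), knockout replicate 1 (0.129) or knockout replicate 3 (0.0884). It also missed it with quantile normalization (0.296), with cyclic loess (0.197), without dim genes (0.153) and without the intensity trend (0.0687). The long-term stem cell genes did not pass (50 genes, median -0.00, mean 0.01, camera adjusted p = 0.927), with 4 members higher and 4 lower at an unadjusted p under 0.05: the transcription factor genes Meis1 and Mycn had 0.39 and 0.48, and Nr4a1 and Ltb -0.27 and -0.53. Nor did the lymphoid-primed progenitor genes pass (36 genes, median 0.06, adjusted p = 0.750), where the homing receptor gene Ccr7 had -0.62, Sox4 -0.36, Dntt -0.25 and Cd53 0.30. The megakaryocyte and erythroid genes did not pass (37 genes, median 0.00, adjusted p = 0.887), with the platelet glycoprotein gene Gp5 at -0.52, Treml1 at -0.45, Tspan33 at 0.63 (0.40 without knockout replicate 2) and Plek at -0.29.

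**Figure D3:**
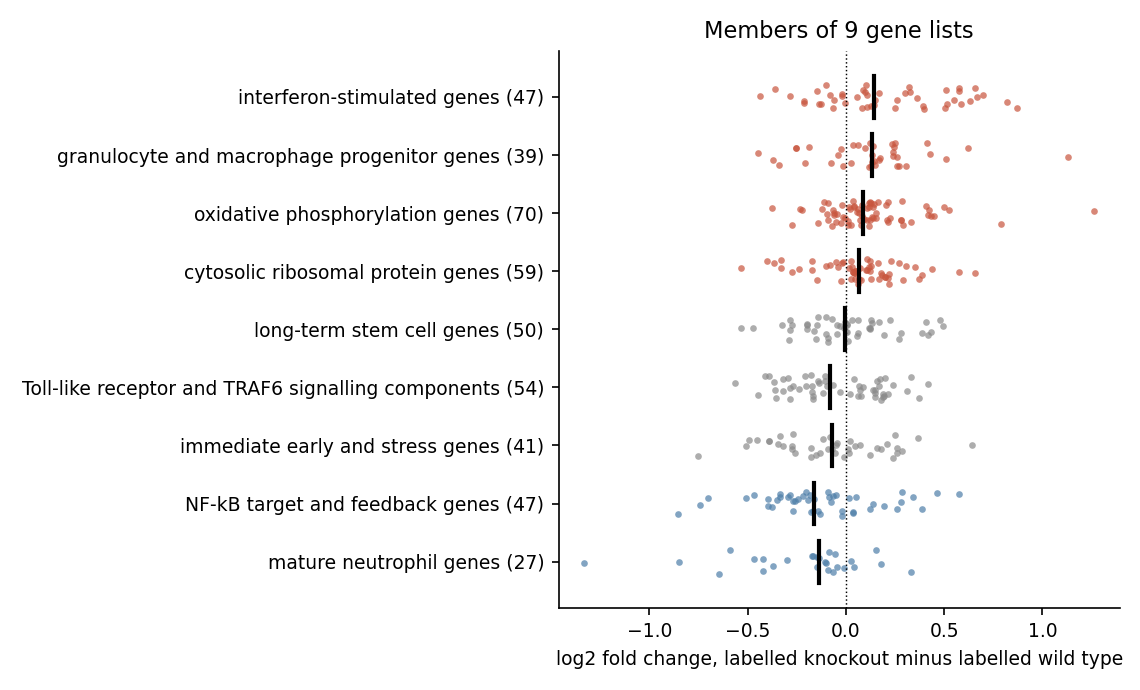
Log2 fold change (knockout minus wild type by label) of each measured member of 9 gene lists, with the number of members in brackets; black bars are medians, and red, blue and grey points mark lists that passed as higher, passed as lower or did not pass the camera test with preset correlation. Medians run from -0.16 for the NF-kB targets to 0.14 for the interferon-stimulated genes, and 0 of 20 lists passed with an estimated correlation; after cyclic loess the ribosomal median was -0.02.

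The cell cycle genes did not pass (58 genes, median 0.04, camera adjusted p = 0.565), with Ccna2, Cdca8 and Rrm2 at 0.40, 0.47 and 0.50 and Tk1 at -0.34. A second probe set of Rrm2 gave -0.11, and the mean of both 0.19; without wild-type replicate 1 the value of Rrm2 was 0.26. The p53 target genes did not pass either (36 genes, median 0.00, mean 0.01, with the test pointing lower at adjusted p = 0.927), with the cell cycle inhibitor gene Cdkn1a at -0.42 and Ccng1, Ddias and Pmaip1 at 0.44, 0.33 and 0.45. With 1 array left out these came down to -0.27 for Cdkn1a, 0.21 for Ddias and 0.17 for Pmaip1. The genes of oxidative phosphorylation rose as a list, 50 of 70 higher with a median of 0.09 (camera adjusted p = 0.00152; adjusted p = 0.579 with an estimated correlation). At an unadjusted p under 0.05, 10 were higher and 0 lower, and Atp5g1 passed adjusted over the list alone (0.0165). Atp5g1 was dim for this list, at 3.51 in the wild-type-labelled and 4.77 in the knockout-labelled arrays, against a mean level of 8.47 over the list. The complex I subunit gene Ndufb3 had 0.79 ± 0.25 (SE), Cox7b, Cox5b and Cycs 0.42 to 0.43, and Atp5k 0.28. A dimmer probe set of Cox5b gave 0.01, one of Cox7b 0.57, and 4 of Cycs, some with the same values as each other, -0.36 to 0.76. The cytosolic ribosomal protein genes rose as a list, 42 of 59 higher with a median of 0.07 (camera adjusted p = 0.00152; adjusted p = 0.319 with an estimated correlation). In this list 11 were higher and 0 lower at an unadjusted p under 0.05, and Rps13 at 0.66 ± 0.13 (SE) and Rpl7 at 0.44 ± 0.09 (SE) passed adjusted over the list alone (0.0228 for both). Rpl23a had 0.37, Rps3a1 0.29, Rplp2 0.57 and Rpl21 0.21. Rplp2 was dim for this list, at 4.38 in the wild-type-labelled and 4.96 in the knockout-labelled arrays, against a mean level of 9.29 over the list. A dimmer probe set each of Rpl7 and Rps3a1 gave -0.24 and -0.46.

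Fold changes also moved with signal level, which bears on these lists of bright genes. The dimmest decile of genes had a median log2 fold change of -0.17, the fifth and sixth deciles 0.06 and the brightest 0.05, and after cyclic loess the decile medians lay between -0.03 and 0.01. Random lists of equally bright genes had a median of 0.06 for the ribosomal list, whose own median of 0.07 lay at percentile 51.2 of them, so it was no higher than other genes of its brightness. The oxidative phosphorylation median lay at percentile 88.6 of its random lists, the granulocyte and macrophage median at 98.3 and the interferon median at 99.9. The neutrophil median lay at 0.02 and the NF-kB median at 0. Some lists that did not pass were as extreme: B and plasma cell at 100, immediate early at 0, Toll-like receptor and TRAF6 at 0.2, and mast cell, basophil and eosinophil at 0.64. The remaining lists that did not pass lay between 10.7 and 73.3. These percentiles leave out correlation between genes and do not separate passing lists from others. With cyclic loess the ribosomal list had a median of -0.02 and turned to lower (camera adjusted p = 0.988, with 0.00154 to 0.988 over all alternatives). The oxidative phosphorylation list then had 0.04 (0.113) and the granulocyte and macrophage list 0.11 (0.197). None of these passed the threshold, while the NF-kB list (0.00206), the neutrophil list (0.00206) and the interferon list (0.00215) did. With an estimated correlation after cyclic loess, the NF-kB, neutrophil and interferon lists missed it, at 0.357, 0.353 and 0.353. The ribosomal list also missed the threshold without the intensity trend in limma (adjusted p = 0.0577). Without wild-type replicate 1 the oxidative phosphorylation list missed the threshold (adjusted p = 0.143).

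**Figure D4:**
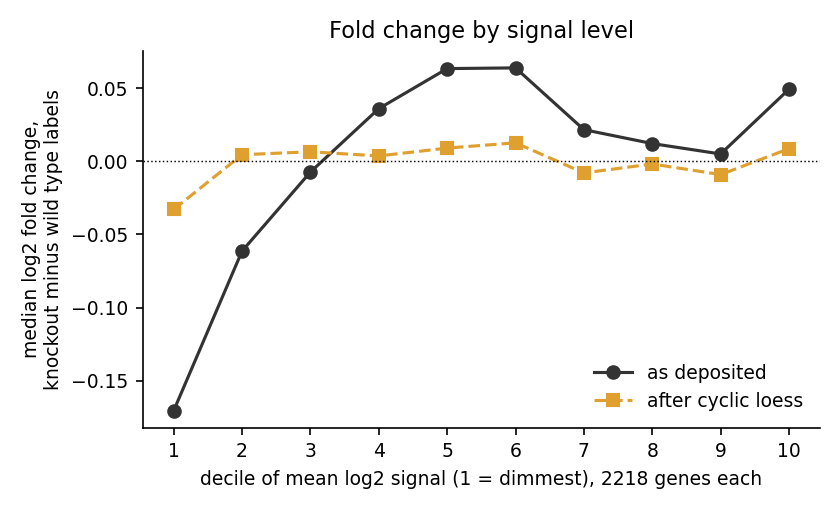
Median log2 fold change (knockout minus wild type by label) of genes in each decile of mean log2 signal, 2218 genes per decile, with the values as deposited (circles) and after cyclic loess between arrays (squares). The dimmest decile lies at -0.17 as deposited and at -0.03 after cyclic loess.

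Markers of other cells that the sort could hold were examined in the same way. The mature neutrophil genes fell as a list: 22 of 27 were lower and 5 higher, with a median of -0.13 (camera adjusted p = 0.0101; adjusted p = 0.319 with an estimated correlation). At an unadjusted p under 0.05, 4 were lower and 0 higher: Il1r2, Ifitm6 at -0.65 ± 0.18 (SE), the collagenase gene Mmp8 at -0.85 ± 0.24 (SE) and Cd177 at -0.42 ± 0.18 (SE), none of which passed adjusted over the list alone. Stfa1 and Trem1 had -0.42 and -0.47, or -0.24 without wild-type replicate 2 and -0.10 without wild-type replicate 3, and Mmp8 had -0.56 without knockout replicate 3. Of the list's 4 brightest genes, S100a8 had -0.06 ± 0.07 (SE), S100a9 -0.01 ± 0.08 (SE), Camp 0.33 ± 0.30 (SE) and Pglyrp1 -0.37 ± 0.32 (SE). Without wild-type replicate 1 the list missed the threshold (adjusted p = 0.0707). The mast cell, basophil and eosinophil genes did not pass (23 genes, median -0.13, camera adjusted p = 0.0883), though the eosinophil chemokine receptor gene Ccr3, at -0.97 ± 0.22 (SE), passed adjusted over the list alone (0.0410). Ccr3 read 3.10 against 2.13, near the bottom of the signal range where dim genes as a whole were lower, so the size of its difference is not resolved. Ms4a2 had -0.57, Epx -0.89 and Prg2 -1.75. Prg2, the eosinophil major basic protein gene, read 6.44, 9.65 and 6.38 in the knockout-labelled arrays against 8.87 to 9.62 in the others. The mast cell, basophil and eosinophil list passed without knockout replicate 2 (adjusted p = 0.00258) or wild-type replicate 2 (0.0321). The macrophage and monocyte genes did not pass (29 genes, median 0.05, mean -0.07, test direction higher, adjusted p = 0.927), with Fabp4 passing as lower adjusted over the list alone (-1.46, 0.0427), at a knockout-labelled mean of 2.63 near the bottom of the signal range that leaves its size unresolved, and C1qa and C1qb at 0.52 and -0.51. The B and plasma cell genes (21 genes, median 0.28, adjusted p = 0.210) included Blk, Fcer2a, Cd79b and Ighm at -0.34, -0.36, 0.40 and 0.19, and 6 other probe sets of Ighm ran from -2.19 to 1.05. The T and NK cell genes (25 genes, median 0.07, adjusted p = 0.413) included Klrd1, Gzmk, Icos and Cd3g at 0.63, 0.51, -0.26 and -0.37. The MHC class II and dendritic cell genes (23 genes, median 0.01, adjusted p = 0.654) had Batf3, Bst2, Ciita and Flt3 at 0.50, 0.32, 0.37 and -0.24. The stromal and endothelial genes (31 genes, median -0.05, adjusted p = 0.541) had Col4a1, Adipoq, Emcn and Egfl7 at -0.41, -0.43, 0.48 and -0.23. Leaving out 1 array made the values of Batf3, Flt3, Cd79b, Fcer2a, Ighm, Cd3g, Adipoq, Emcn, Egfl7 and Ms4a2 over 1.5 times smaller. None of the B and plasma cell, T and NK cell, dendritic cell and stromal lists passed, though the B and plasma cell list did without wild-type replicate 3 (adjusted p = 8.80e-06) or knockout replicate 1 (0.0133). Those calls used camera at the preset correlation of 0.01. The estimated correlation among the B and plasma cell genes was 0.434, which gave an adjusted p of 0.588 with all arrays. Across all 20 lists, fry called 0 as moving 1 way and 4 as changing in either direction. These were the genes next to Tifab (adjusted p = 0.0122), the NF-kB targets (0.0122), the interferon-stimulated genes (0.0376) and the macrophage and monocyte genes (0.0460). The call of the genes next to Tifab rested on Macroh2a1. Tested as a set, the other 23 genes of that list had an unadjusted fry p of 0.144 for either direction. Their positions were not checked.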

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

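The threshold of 8-fold with no overlap between groups, used here for probe sets outside the gene comparison, was chosen after the values were seen. Among the 16010 probe sets that the annotation does not list, 8 met it, 3 higher and 5 lower in the knockout-labelled arrays, while 0 of the 22180 genes reached 8-fold.

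A signal above the level of the wild-type-labelled arrays appeared in 3 probe sets whose genes are not named here. Probe set 17384447 read 7.23, 6.04 and 6.89 in the knockout-labelled arrays against 1.56 to 2.78 in the wild-type-labelled arrays, a log2 difference of 4.44 ± 0.42 (SE) with an adjusted p of 0.0704 over all probe sets in limma. Probe set 17284437 had a log2 difference of 4.92 ± 1.75 (SE, adjusted p = 0.430), with knockout replicate 1 at 3.55 near the wild-type-labelled arrays and the other 2 at 9.32 and 10.99. A further probe set differed by 3.99 ± 1.08 (SE, adjusted p = 0.370), with 1 knockout-labelled array at 8.50 and the other 2 at 4.20 and 4.43. In the other direction, probe set 17208107 read 4.99 to 6.11 in the wild-type-labelled arrays and at most 1.81 in the knockout-labelled arrays, a difference of -3.70 ± 0.32 (SE, adjusted p = 0.0704). The low readings of probe sets 17384447 and 17208107 and of the further one lie near or below the median of the dimmest decile of genes, 2.12, so the sizes of these differences are not resolved. Over all probe sets, 0 passed an adjusted p of 0.05, 18 passed 0.1, and 4203 had an unadjusted p under 0.05.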

How the results depend on the processing

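All alternatives except cyclic loess were planned; cyclic loess was chosen after seeing the data. Over 112 named genes and 1667 pairs of gene and alternative, the direction turned in 2: Tifab, whose log2 fold change ran from -0.25 to 0.017 when each array was left out, and Rps3a1, at -0.085 with the mean of its probe sets. No gene passed under any normalization, filter or variance setting run; with each array left out the count of genes ran from 0 to 1 (Iglv1 without wild-type replicate 3, Prg2 without knockout replicate 2). The looser count of 605 became 356 without dim genes, 51 at 2-fold, and 682 to 1095 with each array left out. Median centring gave 189 higher of 663, or 28.5%, against 47.4% as deposited. The number of lists called, 6 of 20, was 0 with an estimated correlation, 0 by fry and 2 to 8 with each array left out; the 2 without wild-type replicate 1 were the ribosomal and interferon lists. Adjusted p values of lists that lost their call, by alternative, were as follows, and the cause was not tested. With an estimated correlation the NF-kB, interferon, ribosomal and neutrophil lists had 0.319, oxidative phosphorylation 0.579 and the granulocyte and macrophage list 0.612. With fry the same 4 lists had 0.197 and the other 2 0.371 and 0.473. With quantile normalization the ribosomal list had 0.508, oxidative phosphorylation 0.271 and the granulocyte and macrophage list 0.296, and with cyclic loess 0.988, 0.113 and 0.197. Without the intensity trend the ribosomal list had 0.0577 and the granulocyte and macrophage list 0.0687, and the latter had 0.153 without dim genes. With each array left out, NF-kB ran from 0.00280 to 0.143, neutrophil from 0.00280 to 0.0707, oxidative phosphorylation from 9.62e-05 to 0.143, and granulocyte and macrophage from 0.00345 to 0.458. Of the 6 called lists, the ribosomal list turned direction with cyclic loess, and the other 5 kept the direction of the test under all 18 alternatives. Of the lists not called, those that turned direction stayed above the threshold. With quantile normalization the adjusted p was 0.974 for cell cycle, 0.616 for stem cell, 0.881 for lymphoid, 0.878 for macrophage and 0.696 for megakaryocyte and erythroid genes. Without dim genes these were 0.977, 0.575, 0.873, 0.766 and 0.628. With cyclic loess stem cell had 0.710, lymphoid 0.904, macrophage 0.904 and megakaryocyte and erythroid 0.812. With array weights macrophage had 0.951. With each array left out, cell cycle ran from 0.151 to 0.964, stem cell from 0.691 to 0.964, lymphoid from 0.0671 to 0.983, macrophage from 0.432 to 0.964, megakaryocyte and erythroid from 0.703 to 0.964, p53 from 0.703 to 0.964, and MHC class II from 0.396 to 0.983. Lists not called passed in 10 pairs of list and alternative, all at the preset correlation. Among them were immediate early genes in 5, the B and plasma cell list in 2 (8.80e-06 without wild-type replicate 3) and the genes next to Tifab in 1 (0.0362 without dim genes).

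With the replicate number as a block, 0 genes and 6 lists passed, the looser count was 647, Tifab stayed at -0.10, and the macrophage list turned direction at an adjusted p of 0.870. The values gave no sign that the numbers pair the samples: same-numbered arrays had correlations of their deviations from group means of 0.0203, -0.0314 and -0.0880. Differently numbered arrays ran from -0.0740 to 0.107. With 3 arrays per group, these correlations cannot exclude pairing. Signal near the floor of the arrays limits what dim genes can show.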

Other observations

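The genes singled out in the first 3 paragraphs, the zinc-finger comparison and the tests of explanations below were chosen only after the results were seen; the counts over splits were planned.

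Several genes above the median level and outside the named rule had no overlap between groups. Ctla2b, of a family of cysteine protease inhibitors, measured 9.61 ± 0.09 (SD, n = 3) in the wild-type-labelled arrays and 8.88 ± 0.13 (SD, n = 3) in the knockout-labelled arrays, a log2 fold change of -0.74 ± 0.11 (SE, adjusted p = 0.297 in limma). Bex1 went the other way, from 6.55 ± 0.16 to 7.40 ± 0.05 (SD, n = 3 each), a log2 fold change of 0.85 ± 0.14 (SE). Mndal, an interferon-inducible gene of the Ifi200 family that none of the lists held, had 0.88 ± 0.17 (SE), the interferon-inducible Slfn8 0.91 ± 0.20 (SE), and the MHC class I gene H2-T24 0.90 ± 0.18 (SE).

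Some plasma cell genes differed widely among the wild-type-labelled arrays. Jchain read 8.42, 8.99 and 10.39 in the wild-type-labelled arrays and 9.73 to 9.87 in the knockout-labelled arrays, and Iglv1 5.71, 5.79 and 9.45 against 8.39 to 9.03. Mzb1 read 5.15, 5.67 and 8.17 against 6.35 to 6.50. Wild-type replicate 3 was thus the highest wild-type-labelled array for each, and the median deviation of the 21 B and plasma cell genes from their mean over arrays was 0.43 there, 0.34 in knockout replicate 2 and -0.36 in wild-type replicate 2. The estimated correlation among these genes was 0.434. The eosinophil gene Epx varied within the knockout label, at 4.43, 5.80 and 4.42, with knockout replicate 2 highest as for Prg2.

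Zinc-finger genes were counted because they had been seen among the largest differences, so no p is given for them. Of 211 genes named Zfp and a number above the median level, 17 (8.06%) passed the looser threshold, 12 higher and 5 lower, against 275 of 10879 other genes (2.53%), an odds ratio of 3.38. Genes are not independent replicates, and in the other 9 splits of the 6 arrays the odds ratio ran from 0.529 to 3.28.

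The lower Macroh2a1 signal is a hypothesis of an effect at the Tifab locus. An intensity trend between the groups is argued against: the brightest decile, which holds Macroh2a1, had a median log2 fold change of 0.05, opposite in sign. Cyclic loess, which removed the trend, left Macroh2a1 at -0.95 (-0.97 to -0.81 over all alternatives). With a trend that small, the result after cyclic loess could hardly have come out otherwise. A change in most genes across the segment is argued against as well: of 99 other measured genes around Tifab, 8 (8.08%) had an unadjusted p under 0.05. The exact upper 95% limit was 15.3%, below the 95th percentile of 17% over windows around other genes. That limit treats neighbouring genes as independent, and a change in only some genes of the segment is not excluded. An effect of the engineered allele on its neighbour, strain variants under the Macroh2a1 probes and an indirect effect of genotype stay open and were not tested. Positions of the named genes outside the list next to Tifab are not given here, so effects of the locus stay open for them too.

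The lower NF-kB list has several explanations that stay open. Its call also depended on wild-type replicate 1, without which the list missed the threshold (camera adjusted p = 0.143). By the median deviation of its members from their mean over arrays, knockout replicate 1 (0.009) lay above wild-type replicate 3 (0.003). The intensity trend is argued against as the whole cause, since cyclic loess left the median of the NF-kB list at -0.168, against -0.164 as deposited. After cyclic loess the list passed at the preset correlation (camera adjusted p = 0.00206) and missed the threshold with an estimated one (0.357). Over all alternatives, each changing 1 setting, its adjusted p ran from 0.000349 to 0.319. Fewer neutrophils in the knockout-labelled sorts, which a lineage-negative gate should remove, cannot be told apart. Of the 27 neutrophil genes, 24 exceed the median gene in the wild-type-labelled arrays. The 9 most abundant of the 27 had a median of -0.065, between 0 and the -0.16 of the NF-kB list. The standard error of the mean over these 9 genes was 0.06. It treats the genes as independent and does not measure the spread between arrays. Faster handling of the knockout-labelled sorts cannot be told apart either, since the immediate early list missed the threshold as deposited and passed after cyclic loess (camera adjusted p = 0.00215). Over all alternatives, each changing 1 setting, its adjusted p ran from 0.00185 to 0.772. After cyclic loess with an estimated correlation it missed the threshold, at 0.663. An effect of genotype remains possible and was not tested apart from these.

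The higher ribosomal protein list may reflect the intensity trend: after cyclic loess its median went from 0.07 to -0.018 and the call ended. For oxidative phosphorylation the median went from 0.09 to 0.037 and the call ended, but part of the shift stayed, so trend and genotype cannot be told apart for that list. Ndufb3 kept a log2 fold change of 0.77 ± 0.25 (SE) and Atp5g1 1.20 ± 0.21 (SE) after cyclic loess, against 0.79 and 1.26 before. The Atp5g1 probe set was dim for its list, at 3.51 in the wild-type-labelled arrays.

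The 6 arrays make 10 splits into 3 and 3, so a share under 0.05 cannot be reached. For genes past the adjusted threshold the real split gave 0 and the highest other split 1; any of the 10 splits reaches a count of 0, so this comparison carries no information. For the looser count the values were 605 and 348, with 1 split reaching the real value, the real one itself. For lists called they were 6 and 6, with 3 splits reaching the real value.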
